A study of Cricetulus griseus with 5 samples.

How the data were processed

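RNA of A23, a thymidine kinase-deficient Chinese hamster fibroblast line used as the recipient in radiation hybrid panels, was compared with itself on 5 two-colour microarrays. Per the labels' protocols, cells were grown in flasks and harvested with trypsin, total RNA was isolated with a column kit, and 20 µg was directly labelled, with Cy5 in channel 1 and Cy3 in channel 2. The labels number the arrays as replicates 1 to 5. They do not say whether the arrays came from separate cultures, extracts or labellings, so the p-values measure only the spread between these arrays, which may be technical. All 5 arrays carry the dyes the same way round. The deposited table gives no slide or scan date, so no batch could be tested.

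The deposited table holds 1 log ratio of the channels for each of 20868 numbered array features (called probes here) and each of the 5 arrays, with no empty cell. How the images were quantified, background-corrected and dye-normalized is not given in the sources used here. The deposited values were read as log10 ratios. The basis for this is that each column is centred exactly at a median of 0, that values of both signs lie between -1.72 and 1.35, and that 6.43% to 20.8% of each column is exactly 0, a form that Agilent's log10 ratio column takes. Neither the log base nor the channel in the numerator is stated, so ratios are reported by their sign alone, folds hold only under the log10 reading, and a log2 reading is carried as an alternative. Tests against a ratio of 0, correlations over all probes and percentiles do not depend on the base, but every value that uses a fold limit does, such as the calls against a minimum of 1.2-fold and the correlation without probes beyond 2-fold. The deposited table holds no signal intensity, so the brightness behind a ratio is unknown, and the number of arrays sets the precision. The table has 0 columns of samples outside the series.

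Gene names came from the array platform's annotation table, which names mouse genes. Of the probes, 17786 had 1 gene symbol, 16 had several and 3066 had none, and only those with 1 symbol were named, giving 16504 genes. Symbols could not be updated, because the gene table at hand is of the hamster. No genome position is given, since no mouse genome was used here.

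Log ratios were converted to log2 (a factor of 3.32) and fitted in limma 3.58.1 under R 4.3.3 with an intercept alone (lmFit, eBayes), which tests each probe's mean ratio against 0. Benjamini-Hochberg adjustment ran over all 20868 probes with a threshold of 0.05. For genes, probes of 1 symbol were averaged first; of the 1152 genes with several probes, 543 had probe means of both signs. Values are printed in the deposited log units as mean ± SD over n = 5 arrays. The smallest detectable fold was computed from each probe's own SD for a two-sided one-sample test at an unadjusted alpha of 0.05 and a power of 0.8. Correlations between arrays are across probes, which are not independent replicates.

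The design of each test, the alternatives and 25 gene lists were fixed before the data were examined. The lists were ribosomal proteins, translation factors, proteasome, glycolysis, oxidative phosphorylation, chaperones, unfolded protein response, DNA replication, mitosis, core histones, extracellular matrix, actin cytoskeleton and cholesterol synthesis as genes a growing fibroblast line uses; immediate early and interferon response genes; and markers of epithelial, endothelial, macrophage, lymphocyte, erythroid, neuron, hepatocyte, skeletal muscle, adipocyte and male germ cells. Core histones were not tested, since 2 of their 55 symbols matched and 5 were required. The other 24 lists were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Between-array SD of a list (per gene the median over its probes) was set against 10000 random gene lists of the same size.

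The genes named were set by a rule: among probes with 1 symbol that passed the threshold with 1 sign on all 5 arrays, the 10 largest mean ratios of each sign; the 5 named probes with the largest between-array SD; 8 fixed genes (Tk1, Hprt, Actb, Gapdh, Eef1a1, Vim, Col1a1 and Fn1, of which Gapdh had no named probe); and up to 4 members per list with the smallest p. Members named for an exact 0 were chosen after their values were seen.

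The probe fit was tested on simulated data with the real between-array SDs on 20868 probes: it recovered 43.3% of probes shifted 1.5-fold, 61.2% of those shifted 2-fold and 93.9% of those shifted 4-fold, with 10 false calls. In the list test, run on 16504 simulated genes, the 1 list shifted by 0.15 log2 units was called and 0 of 23 others were. Simulated genes were drawn independently of each other, so this run cannot show how often lists of co-varying genes are called falsely. The alternatives fixed together with the gene lists were median centring, scaling, quantile normalization, robust and weighted fits, a plain one-sample test per probe, a minimum size of 1.2-fold, the log2 reading and leaving out each array. Treating exact zeros as missing, keeping only probes with no exact zero, and subtracting a local median over a window of 7 by 7 neighbouring features (the row length was inferred from the correlation between features) were added after seeing the data, as were the 2 scalings for gene lists. Figures were drawn with matplotlib 3.10.9.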

Results

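Self-self hybridisations of A23 hamster cells were made on mouse-gene microarrays, with that cell line's RNA in both channels of each of 5 arrays. Per the series' design text they are controls for how much power the radiation hybrid experiment has to find cis ceQTLs, which are loci whose copy number acts on the expression of a gene at the same place. All 5 arrays form 1 group, and each gave a log ratio for 20868 probes, of which 17786 had a single gene name. With RNA of 1 cell line in both channels a ratio of 0 is the value the design implies, so the comparisons below concern which genes departed from it, by how much, and how far arrays differed. The sign of a ratio is that of the deposited value; which dye it favours is not stated.

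Ratios were close to 0 for most genes on every array, with a minority far from it. The SD of the log ratios within an array was 0.133 ± 0.0235 (SD, n = 5 arrays), and the interquartile range was 0.0838 ± 0.0167. Read as log10, 11.7% ± 4.43 (SD, n = 5) of the probes lay beyond 1.5-fold and 4.31% ± 2.34 beyond 2-fold. Replicate 2 was the widest, with an SD of 0.174 and 8.47% of probes beyond 2-fold, against SDs of 0.119 to 0.127 and shares of 2.96% to 3.68% on the other arrays. Without replicate 2 the mean SD was 0.122. An exact 0 was listed for 11.5% ± 5.62 (SD, n = 5) of the probes of an array, from 6.43% on replicate 4 to 20.8% on replicate 5, and 412 probes were listed at 0 on all 5 arrays.

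The first question was which genes gave a ratio other than 0 although both channels held A23 RNA. In limma's moderated test with Benjamini-Hochberg adjustment, 713 of 20868 probes passed an adjusted p of 0.05, 295 with a positive and 418 with a negative ratio, and at an unadjusted p of 0.05 the number was 5689 (27.3% against the 5% that chance gives). All 713 had 1 sign on the 5 arrays, which passing this threshold with 5 values all but requires. Over all probes, called or not, 26.4% had 1 sign, where chance gives 6.25%. Under the log10 reading, 234 of the 713 were under 1.2-fold. Of the 85 called probes beyond 2-fold, 79 were negative and 6 positive. Over all probes of a single array the balance was the other way on 4 of the 5 arrays: beyond 2-fold, replicates 1, 2, 3 and 5 had 511, 1102, 449 and 339 positive against 192, 665, 192 and 279 negative probes, and replicate 4 had 325 against 442. At the level of genes, 405 of 16504 passed, 174 positive and 231 negative, and 4573 had an unadjusted p under 0.05. The counts rested on having 5 arrays: leaving out replicate 1, 2, 3, 4 or 5 left 24, 4, 5, 8 or 63 probes, while the share of all probes with an unadjusted p under 0.05 was 21.1% to 25.4%.

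Among called probes, the negative extremes were single probes. Ppp2r5e, a regulatory subunit of protein phosphatase 2A (feature 5206), had a log ratio of -1.50 ± 0.163 (SD, n = 5), which is 31.4-fold if log10 and 2.82-fold if log2 (limma adjusted p = 0.00696). Gad1, a glutamate decarboxylase that makes the transmitter GABA (feature 4463), stood at -1.40 ± 0.098 (adjusted p = 0.00246), and Svop, a synaptic vesicle protein, at -1.25 ± 0.118 (adjusted p = 0.00525). Ccdc30 at -1.21 ± 0.194, the acetyltransferase gene Kat14 at -1.18 ± 0.161, the cytokine gene Il3 at -1.18 ± 0.135 and the orphan receptor gene Gpr149 at -1.09 ± 0.402 followed. Aldh6a1, a mitochondrial aldehyde dehydrogenase, gave -1.08 ± 0.231, 1700102P08Rik -1.05 ± 0.113 and Krit1 -0.966 ± 0.0468, with an adjusted p of 0.00134 for Krit1 in limma, the lowest of the named genes. For every one of these 10 genes, all 5 arrays had a negative ratio, which the naming rule required.

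Among called probes, positive mean ratios reached a lower size than negative ones. Zmym5 (feature 20626) led with 0.499 ± 0.169 (SD, n = 5), 3.15-fold if log10 (limma adjusted p = 0.0432). The neuron navigator gene Nav1 had 0.386 ± 0.0819, Ccdc88c 0.344 ± 0.0886, Gdpd5 0.337 ± 0.0624, the cornified envelope gene Lce1f 0.291 ± 0.0968 and the transcription factor gene Batf3 0.290 ± 0.106. Chn2, which encodes a chimaerin, had 0.287 ± 0.0494, the autophagy gene Atg2a 0.283 ± 0.0287, S100pbp 0.269 ± 0.0677 and Tmem106b 0.252 ± 0.0588. Of these 20 genes, Gad1 and Krit1 passed under every alternative run for single genes and every left-out array, and the other 18 lost the call at least once. The fit restricted to probes with no exact zero was not among those alternatives. Sizes moved less than calls in the examples of Ppp2r5e, at -1.55 to -1.44, and Atg2a, at 0.276 to 0.292, when each array was left out.

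**Figure D1:**
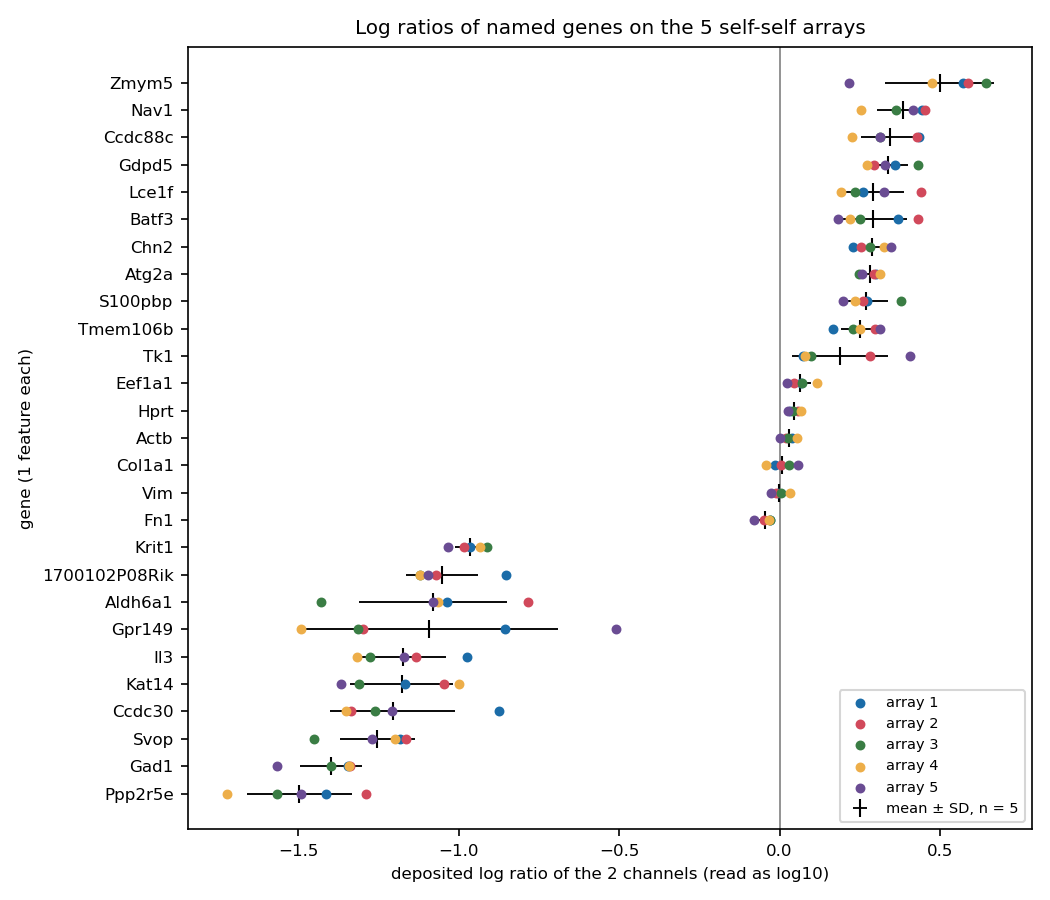
Deposited log ratio (horizontal axis, read as log10) of the 10 most negative and 10 most positive called genes and 7 fixed genes (vertical axis), 1 feature each, with a point per array and a bar for mean ± SD over 5 arrays. The called genes run from Ppp2r5e at -1.50 to Zmym5 at 0.499, while Actb, Vim and Col1a1 lie near 0. The naming rule required 1 sign on all 5 arrays of the called genes.

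Genes fixed in advance as common references did not pass the threshold in the moderated test as planned; with array weights Hprt (adjusted p = 0.0449 in limma) and Eef1a1 (0.0436) did. Tk1, the thymidine kinase whose activity A23 cells lack, had a ratio of 0.188 ± 0.149 (SD, n = 5; limma adjusted p = 0.134) and was positive on each array. Hprt, a purine salvage enzyme, gave 0.0452 ± 0.0166 (adjusted p = 0.0662 in limma) and the elongation factor gene Eef1a1 0.0645 ± 0.0348 (adjusted p = 0.0833 in limma). The fibronectin gene Fn1 gave -0.0443 ± 0.0218 (adjusted p = 0.0866 in limma), and beta-actin (Actb) gave 0.0285 ± 0.0203. The collagen gene Col1a1 stood at 0.0069 ± 0.0391 and vimentin (Vim) at -0.000819 ± 0.0221, both smaller than their spread between arrays.

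Groups of genes were then compared with all other genes. Ribosomal protein genes and genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, had positive ratios as groups. The median over 59 ribosomal protein genes was 0.0436, 1.11-fold if log10, with 51 positive and 8 negative means (camera adjusted p = 7.32e-09), a call that was lost with an estimated correlation between genes (adjusted p = 0.741). The median over 58 oxidative phosphorylation genes was 0.0499, 1.12-fold if log10, with 48 positive and 10 negative (camera adjusted p = 9.94e-10), and this call too was lost with an estimated correlation (adjusted p = 0.741). Both medians were positive on each of the 5 arrays and highest on replicate 4, at 0.0851 and 0.0811. A positive median on each array was also seen for lists that did not pass camera. These were translation factors, glycolysis, extracellular matrix, cholesterol synthesis and immediate early genes, while the macrophage median was negative on each array. The lowest of these positive medians were barely above 0, with translation factors at 0.00062 and extracellular matrix at 0.000414 on replicate 5. Singly, 3 ribosomal protein genes passed over all genes tested, all positive, and adjusted over the list alone 32 were positive and 2 negative. For oxidative phosphorylation 8 passed, all positive, and adjusted over the list alone 39 were positive and 3 negative. Rps23 had 0.084 ± 0.0198 (SD, n = 5), Rpl41 0.0909 ± 0.0269 and Rpl36 0.0755 ± 0.0208, while Rplp1 at 0.115 ± 0.0441 had a limma adjusted p of 0.0504. Cox8a, a subunit of cytochrome c oxidase, had 0.111 ± 0.0255, and the ATP synthase genes Atp5g2, Atp5g1 and Atp5d had 0.101 ± 0.0221, 0.0939 ± 0.0221 and 0.0678 ± 0.0117. In fry, which asks only whether a list's genes move one way, oxidative phosphorylation had an adjusted p of 0.0272 and ribosomal proteins 0.0684.

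**Figure D2:**
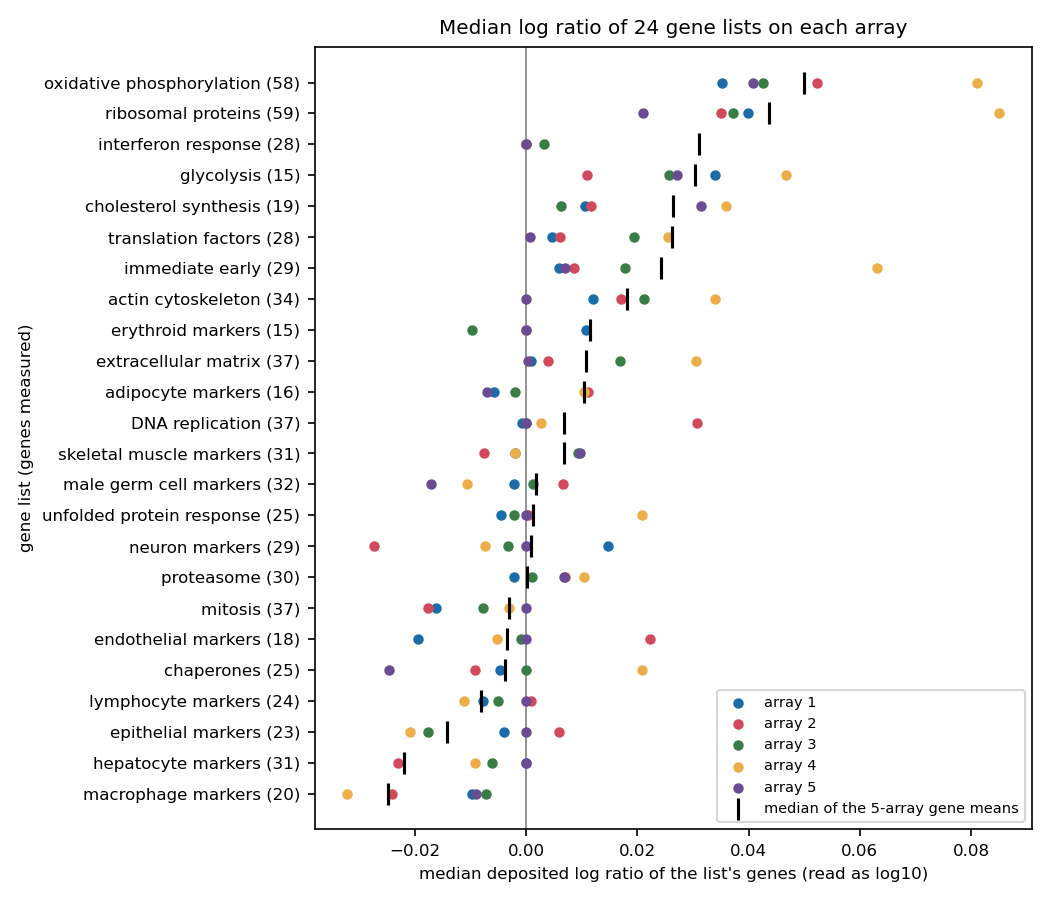
Median deposited log ratio (horizontal axis, read as log10) of each of 24 gene lists (vertical axis, with the number of genes measured), with a point per array and a black tick for the median of the 5-array gene means. Ribosomal proteins and oxidative phosphorylation lie above 0 on all 5 arrays, with medians of 0.0436 and 0.0499. So do translation factors, glycolysis, extracellular matrix, cholesterol synthesis and immediate early genes, in part barely, with extracellular matrix at 0.000414 on replicate 5.

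No other list passed camera, and members of single lists went both ways. Among translation factors (median 0.0262, camera adjusted p = 0.145), Eif3h was negative at -0.0452 ± 0.0049 (SD, n = 5) and was the 1 gene called. Glycolysis (median 0.0304, adjusted p = 0.126) had 0 genes called over all genes and 5 adjusted over the list alone: Hk2, a hexokinase, stood at 0.0912 ± 0.0324 and Pfkp, a phosphofructokinase, at -0.112 ± 0.0425. Chaperones (median -0.00372, adjusted p = 0.692) held Cct8, a subunit of the cytosolic chaperonin, at -0.100 ± 0.0245 and the heat shock protein gene Hsph1 at 0.0762 ± 0.0174, both called. The proteasome (median 0.000105, adjusted p = 0.692) had 0 called over all genes and 8 adjusted over the list alone, 6 positive and 2 negative, with Psmb2 at 0.0514 ± 0.0173. The unfolded protein response (median 0.00125, adjusted p = 0.999) had 0 called over all genes and 9 of 25 adjusted over the list alone, 5 positive and 4 negative, with Herpud1 at 0.064 ± 0.0275 and Atf4 at -0.0723 ± 0.0279. DNA replication (median 0.00677, adjusted p = 0.652) had the helicase gene Mcm2 called at 0.0756 ± 0.0132, and mitosis (median -0.00302, adjusted p = 0.416) had the motor gene Cenpe at -0.0828 ± 0.0186 and the topoisomerase gene Top2a at -0.142 ± 0.0409 called. Extracellular matrix (median 0.0107, camera adjusted p = 0.4999) had the laminin gene Lamb1 called at -0.0699 ± 0.0145. The actin cytoskeleton (median 0.0182, camera adjusted p = 0.126) had Actn4 called at 0.0902 ± 0.0279. Cholesterol synthesis (median 0.0265, camera adjusted p = 0.221) had Dhcr7 called at 0.109 ± 0.0388. Immediate early genes (median 0.0243, adjusted p = 0.193) had Junb, Jund and Gadd45b called at 0.083, 0.0883 and 0.0877, and the median was 0.0124 without replicate 4. Interferon response genes (median 0.0311, adjusted p = 0.821) had Ddx58, Usp18 and Bst2 called at -0.295 ± 0.0388, -0.319 ± 0.0819 and -0.0758 ± 0.0195, opposite in sign to the list's median. Medians near 0 had no settled sign: after quantile normalization that of the proteasome was -0.000244 and that of the unfolded protein response -0.000362, and with single arrays left out those of chaperones and mitosis reached 0.00219 and 0.000404. Counts adjusted over the list alone were 2 positive and 5 negative for chaperones, 1 and 3 for mitosis, 6 and 3 for extracellular matrix, 5 and 1 for immediate early and 1 and 3 for interferon response genes. By that measure the actin cytoskeleton had 3 positive genes, DNA replication and cholesterol synthesis 1 positive gene each, and translation factors 1 negative gene.

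Markers of other cell types did not pass as lists either. Medians were -0.0143 for epithelial (camera adjusted p = 0.522), -0.0035 for endothelial (0.908), -0.0248 for macrophage (0.126), -0.00816 for lymphocyte (0.692), 0.0115 for erythroid (0.999), 0.00092 for neuron (0.684), -0.0219 for hepatocyte (0.652), 0.00675 for skeletal muscle (0.999), 0.0105 for adipocyte (0.821) and 0.00177 for male germ cell markers (0.666). The neuron median was negative with any array left out (-0.0186 to -0.00626), after scaling (-0.0123) and after quantile normalization (-0.0169), and the male germ cell median was -0.000486 after scaling. The hepatocyte median was -0.00671 without replicate 1 and -0.0054 without replicate 2, the macrophage median -0.0151 without replicate 4 and the epithelial median -0.00689 without replicate 3. Single genes called were the desmosome gene Dsp at -0.510 ± 0.0692 (SD, n = 5), Egfl7 at 0.0784 ± 0.0238, Cd37 at -0.478 ± 0.0789, Gad1 and the calcium pump gene Atp2a1 at -0.0806 ± 0.024. Cd37 rested mainly on 1 of its probes, at -0.856 against -0.0992 for the other. Counts adjusted over the list alone were 2 positive and 2 negative for epithelial and 1 and 2 for endothelial markers. By that measure macrophage and hepatocyte markers had 3 negative genes each, lymphocyte, erythroid, neuron and skeletal muscle markers 1 negative gene each, adipocyte markers 1 positive gene and male germ cell markers 0. In fry the macrophage and neuron lists each had an adjusted p of 0.0272; the mean over the neuron genes was -0.0518, opposite in sign to their median, with Gad1 at -1.40 among the 29. Median, mean and test also differed in sign for the unfolded protein response (mean -0.00132, test negative), endothelial (mean 0.01, test negative), hepatocyte (mean 0.0077, test negative) and male germ cell genes (mean 0.0104, test negative).

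Arrays differed less in the genes of lists a fibroblast line uses than in markers of other cell types. The between-array SD of a probe had a median of 0.0588 log units, with a 5th to 95th percentile of 0.0113 to 0.228. Over 406 genes of the lists a growing fibroblast line uses, the median SD was 0.029, against 0.0686 over 239 markers of other cell types, 2.36 times as much (permutation test on the medians, two-sided, p = 1e-05, the smallest that 100000 permutations can give). That test treats genes as independent, but genes of 1 list can co-vary over the arrays (estimated correlation 0.597 for ribosomal proteins). Its p-value therefore overstates the evidence, and those from random lists below can do so too. Of the 24 lists, 8 had a median SD below random lists of the same size and 0 above: ribosomal proteins (0.0292), translation factors (0.0277), proteasome (0.0183), oxidative phosphorylation (0.0252), chaperones (0.0219), unfolded protein response (0.0275), actin cytoskeleton (0.024) and immediate early genes (0.0312), with adjusted p-values from 0.00096 to 0.0312. Glycolysis (0.0302), extracellular matrix (0.0375), mitosis (0.0409), DNA replication (0.0432) and cholesterol synthesis (0.0448) did not pass. Nor did adipocyte (0.0443), macrophage (0.0531), epithelial (0.0595), neuron (0.063), skeletal muscle (0.0664), lymphocyte (0.0688), endothelial (0.0707), erythroid (0.0739), male germ cell (0.0764) and hepatocyte markers (0.088) or interferon genes (0.078). The call for immediate early genes was lost without replicate 1, 2, 3 or 5 (adjusted p = 0.124, 0.063, 0.054 and 0.217), and that for translation factors without replicate 2 (0.088). Among probes with no exact zero, the calls for the unfolded protein response (adjusted p = 0.074) and immediate early genes (0.128) were lost, which left 6 lists. Without replicate 4, glycolysis (adjusted p = 0.0101) and extracellular matrix (0.0048) passed below random lists, and without replicate 5 hepatocyte markers passed above them (0.0264).

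Exact zeros were also unequal between gene lists. Of 16504 genes, 25.3% had a probe listed at exactly 0 on at least 1 array. The share was 0 of 58 for oxidative phosphorylation, 2 of 59 for ribosomal proteins, 1 of 25 for chaperones and 2 of 30 for the proteasome, and ran up to 18.9% for DNA replication and mitosis among the lists a fibroblast line uses. It was 42.9% for interferon response genes and 6.9% for immediate early genes. Among markers of other cell types it was 40% for macrophage, 33.3% for endothelial and erythroid, 28.1% for male germ cell, 27.6% for neuron, 26.1% for epithelial, 25.8% for hepatocyte, 25% for lymphocyte, 19.4% for skeletal muscle and 12.5% for adipocyte markers. Against all other genes, oxidative phosphorylation (Fisher's exact test, adjusted p = 1.42e-06 over 24 lists) and ribosomal proteins (adjusted p = 0.000165) were listed at 0 less often, and no other list passed. The 7 genes of these lists whose single probe was listed at 0 on all 5 arrays were Ptprc and Mrc1 of the macrophage list, Cxcl10 and Oas1g of the interferon list, Il7r of the lymphocyte list, Myf5 of the skeletal muscle list and Psmc6 of the proteasome list. Rps4x, a ribosomal protein gene that every cell uses, was listed at 0 on 4 arrays.

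**Figure D3:**
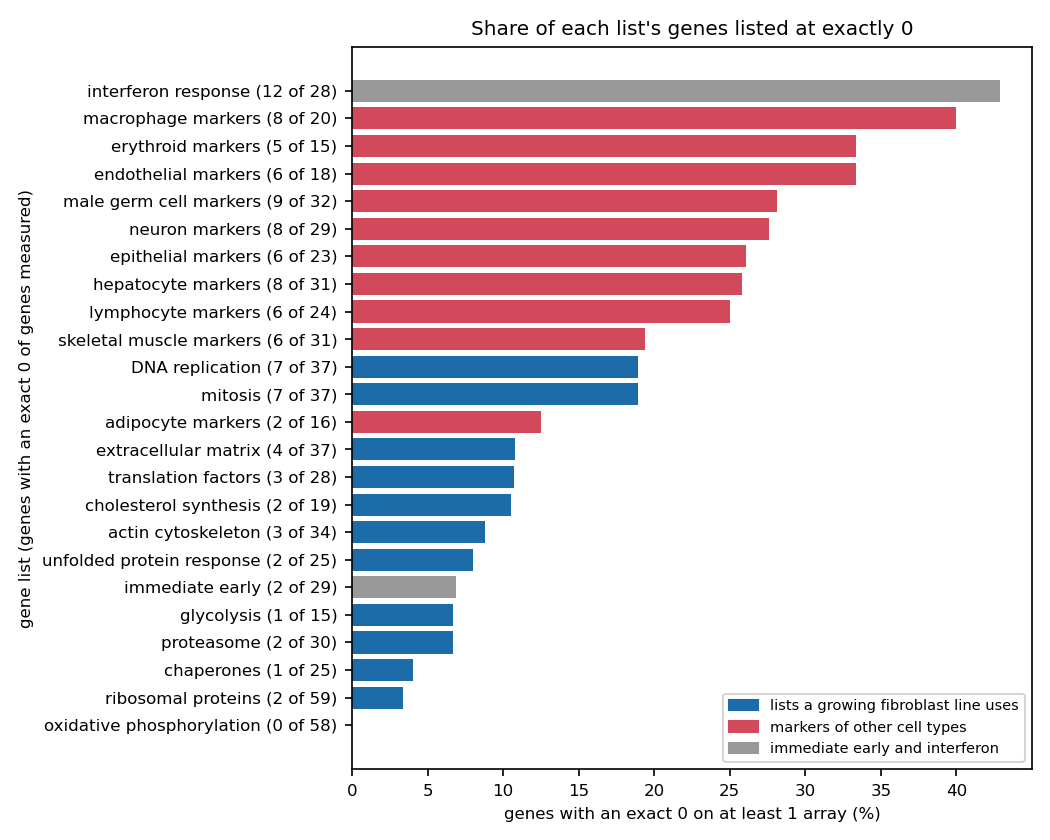
Share of each list's genes with an exact 0 on at least 1 array (horizontal axis, percent), with lists on the vertical axis and colours for the 3 kinds of list. The shares run from 0 of 58 genes for oxidative phosphorylation to 12 of 28 for interferon response.

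The ratios of the same probes on different arrays were correlated although both channels held A23 RNA. Pearson's r across probes was 0.348 on average over the 10 pairs of arrays, from 0.268 between replicates 1 and 5 to 0.424 between replicates 3 and 4. Replicate 5, which had the most exact zeros, had the lowest mean correlation with the others, 0.294, against 0.353 to 0.379. No pair of arrays held identical values. Neighbouring features on an array also resembled each other: r was 0.103 to 0.208 between consecutive feature numbers and 0.121 to 0.202 between features 1 inferred array row apart, but -0.0155 to 0.0264 between features separated by about part of a row.

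The power question was how small a fold 5 such arrays could detect. Under the log10 reading, the median smallest detectable fold was 1.26, and 1.54 at the 75th percentile and 2.42 at the 95th percentile of the between-array SD. A radiation hybrid with 1 donor copy beside the recipient's pair has 3 copies against 2, which is 1.5-fold in copy number. For an expression ratio of that size, 72.1% of the probes had a power of at least 0.8, at an unadjusted alpha of 0.05. For 2-fold the share was 90.2%. With Bonferroni adjustment over all probes the shares were 3.09% and 6.96%. All these shares count as powered the 412 probes (1.97%) listed at 0 on all 5 arrays, since their SD is 0. Much of the Bonferroni shares can therefore be probes without a measured ratio. Among probes with no exact zero, the unadjusted shares were 80.8% and 95%, and the median smallest detectable fold was 1.2. If the deposited values are log2, the median smallest detectable fold is 1.07 and 99.1% of the probes reach the power for 1.5-fold. These values take the true ratio of a self-self array as 0 and leave out the shared departures described above. They rest on the spread between self-self arrays of 1 line, not between hybrid clones, and whether expression follows copy number was not tested.

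**Figure D4:**
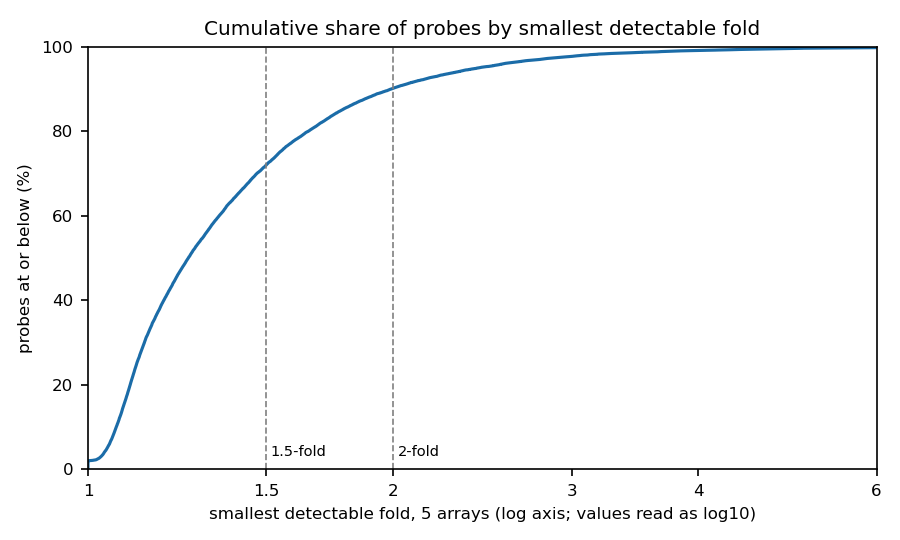
Cumulative share of the 20868 probes (vertical axis, percent) by the smallest fold that 5 arrays detect with a power of 0.8 (horizontal log axis, values read as log10), with dashed lines at 1.5-fold and 2-fold. The curve crosses 1.5-fold at 72.1% and 2-fold at 90.2% of the probes.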

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

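The tests of dye orientation and of low signal, and the sizes of called probes after the local median was subtracted, were chosen after the results they bear on were seen. Subtracting the local median was itself added after seeing the data. Tests that name the ribosomal protein and oxidative phosphorylation lists, or replicate 5, followed the results that single these out. The series has 1 group, so no biological explanation was tested. A single array stood apart from the other 4 by Dixon's criterion in 10 of the 63 sets of 5 values examined. Chance flags about 1 in 20 independent sets, which is no measure for this number: the sets overlap, some probes were chosen for a large SD, and Gpr3 and the interferon median are at 0 on the other 4 arrays. Replicate 2 had the widest ratios, with an SD of 0.174 against 0.119 to 0.127 and 8.47% of probes beyond 2-fold against 2.96% to 3.68%. Replicate 2 stood apart in the ratios of Gorasp1 (1.35, against 0 to 0.161) and of Gpr3 (1.29, against 0 on the other arrays), 2 of the 5 most variable named probes, and the DNA replication list's median (0.0308, against -0.00079 to 0.00273). Replicate 4 stood apart in the median of the unfolded protein response (0.0209, against -0.00447 to 0.000269) and of immediate early genes (0.0632, against 0.00592 to 0.0178). Replicate 3 stood apart in the interferon median (0.00321, against 0), replicate 5 in Gad1 (-1.57, against -1.40 to -1.34) and replicate 1 in 1700102P08Rik (-0.853, against -1.12 to -1.07). The other highly variable probes were Laptm4b (0.0441 ± 0.609, SD, n = 5), Tspan1 (0.0837 ± 0.576) and Sycp1 (0.311 ± 0.573).

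The first pattern is that arrays share ratios, with a mean correlation of 0.348 over pairs and 713 probes called. Local trends over neighbouring features do not account for the correlation: after each array's local median was subtracted it was 0.377. A probe has the same feature number on every array, so position effects finer than the window cannot be told apart from the probe. After the subtraction the median size over the 713 probes was 0.0944 (0.0977 before), although 281 probes were then called, 258 of them among the 713. For the 455 calls lost the median size went from 0.079 to 0.0732 and the median between-array SD from 0.0229 to 0.0282. A few extreme probes do not account for the correlation either, since it was 0.282 without the 3366 probes beyond 2-fold (log10 reading) on any array. A difference in RNA content between the channels would be shared by probes of 1 gene if both read its RNA. Over 1152 genes the mean ratios of a gene's probes correlated at 0.0108, within the range of 100 random pairings (highest 0.0865). The correlation was 0.109 over the 398 pairs of probes for 1 accession and -0.0353 over pairs of different accessions. The highest random value is for all 1152 genes. Fewer pairs vary more by chance, so it is no measure for these subsets. How well mouse probes match hamster RNA was not tested, so the low correlation cannot set RNA content aside. A dye or channel effect tied to the probe also stays open and cannot be told apart, because 0 of the 5 arrays had the dyes the other way round.

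Of the 16 assignments of sign to the 5 arrays, 1 gave as many calls, the real one with 713, and the highest other gave 0; 16 are too few for a share under 0.05.

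The second pattern is the positive ratio of ribosomal protein and oxidative phosphorylation genes, with a median of 0.0478 over 117 genes. It is not the work of 1 array, since the lowest median of the 5 arrays was 0.0328. Nor is it that of local trends on the array, since the median was 0.0443 after the local median was subtracted. Low between-array spread, used as a stand-in for bright probes, did not give such a median in randomly drawn genes. Of 10000 random lists matched on SD, 0 reached it, and the highest had 0.0194. Randomly drawn genes need not co-vary as the lists' genes do, with estimated correlations of 0.597 (ribosomal proteins) and 0.322 (oxidative phosphorylation). The draws therefore cannot show how often co-varying genes reach such a median. With an estimated correlation neither list passed camera (adjusted p = 0.741 for each). A dye or channel effect stays open and cannot be told apart, with 0 arrays of the opposite orientation. Transcript length, labelling and true signal brightness were not tested.

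The third pattern is that exact zeros fell more on some gene lists than on others: 34 of 435 probes of the lists a fibroblast line uses had one (7.82%), against 69 of 269 probes of markers of other cell types (25.7%; Fisher's exact p = 1.64e-10). Mouse probes without a hamster gene of the same name do not account for the difference, since it stayed among probes whose symbol is also a hamster gene's (8.56% against 26.6%, Fisher's exact p = 7.6e-09). Replicate 5, with the most zeros, does not either, since it stayed without that array (4.6% against 16.7%, Fisher's exact p = 1.49e-07). Whether an exact 0 stands for a signal too low to give a ratio stays open, because the table holds no signal and the first comparison is the pattern itself. Genes that every cell uses, such as Psmc6 on 5 arrays, were listed at 0 as well, and how well mouse probes match hamster RNA was not tested.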

How the results depend on the processing

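Median centring changed nothing, because each array's median already was 0. The 713 probes called became 956 after scaling, 529 after quantile normalization and 578 with exact zeros as missing, but 250 in a robust fit, 379 in a plain one-sample test per probe, 281 with the local median subtracted, 52 against a minimum of 1.2-fold, 1581 with array weights and 1325 among probes with no exact zero. The sign split of 295 positive to 418 negative moved to 463 to 493 after scaling, 738 to 843 with array weights, 176 to 353 after quantile normalization, 69 to 181 in the robust fit, 71 to 210 with the local median subtracted and 4 to 48 against 1.2-fold. Leaving out 1 array left 4 to 63 probes and 3 to 64 genes, depending on which array was left out. Each of these fits had 4 arrays, so the number of arrays does not account for that range. Without replicate 5, 55 of the 63 were among the 713. The 405 genes became 747 with the probe of smallest SD, 1069 without probes holding a 0 and 253 with the local median subtracted; the causes of these shifts were not tested. The mean spread within an array was 0.0619 by the median absolute deviation, against 0.133. The mean correlation between arrays was 0.473 among probes with no exact zero and 0.282 without probes beyond 2-fold. The median detectable fold was 1.07 under the log2 reading and 19.6 with Bonferroni, where 3.09% and 6.96% of probes had the power for 1.5-fold and 2-fold. Those shares include the probes listed at 0 on every array. The ribosomal protein and oxidative phosphorylation lists passed camera under every alternative run with the preset correlation and with each array left out, as 2 lists, but neither did with an estimated correlation (adjusted p = 0.741 for each); without probes holding a 0, macrophage markers passed too (-0.0331, adjusted p = 0.0294). When the size of the mean ratio took the place of the SD, 1 of the 8 lists kept its call, the proteasome (percentile 0.14, adjusted p = 0.036), and hepatocyte markers passed above random lists (99.9, adjusted p = 0.0336), 2 in all; percentiles then were 86.9 for ribosomal proteins, 97.7 for oxidative phosphorylation, 51 for immediate early, 19.7 for endothelial and 74.9 for macrophage genes. Other changes of direction were in values short of the threshold: the erythroid list was -0.00784 without probes holding a 0 and 0.00403 (camera negative) after scaling, and Vim was 0.00186 with array weights. With each array left out in turn, medians ran from -0.00307 to 0.00411 for the unfolded protein response, -0.00176 to 0.00606 for the proteasome, -0.00848 to 0.00219 for chaperones, -0.00778 to 0.000404 for mitosis, 0.00535 to 0.0189 for DNA replication, 0.00873 to 0.018 for extracellular matrix, 0.0124 to 0.0287 for immediate early, -0.0186 to -0.00626 for neuron, -0.0273 to -0.0054 for hepatocyte, -0.0102 to 0.012 for male germ cell, -0.029 to -0.0151 for macrophage, -0.0186 to -0.00689 for epithelial, -0.019 to -0.000896 for lymphocyte, 0.0151 to 0.034 for interferon, -0.0111 to 0.00796 for endothelial, -0.00359 to 0.0236 for erythroid and 0 to 0.0167 for skeletal muscle genes; the SD percentile ran from 35.9 to 95.1 for interferon, 46.1 to 72.4 for epithelial, 40.2 to 85.2 for endothelial, 41.1 to 85.9 for lymphocyte and 39.9 to 78.8 for neuron genes; and ratios ran from -0.187 to 0.242 for Laptm4b, 0 to 0.324 for Gpr3, -0.0621 to 0.324 for Tspan1, -0.00583 to 0.0195 for Col1a1 and -0.00941 to 0.00538 for Vim. No paired analysis was possible because the series has 1 group. Without signal intensities, the limit that signal over background sets could not be given.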

Other observations

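Gene families outside the fixed lists, chosen after the zeros had been seen, differed in how often they were listed at 0. Olfactory receptor genes, the odorant receptors of the nose, had an exact 0 on at least 1 array for 336 of 776 probes (43.3%, against 23.3% of the other named probes; Fisher's exact test, adjusted p = 2.28e-32 over 5 families). Vomeronasal receptor genes had one for 63 of 119 probes (52.9% against 23.9%, adjusted p = 3.71e-11) and zinc finger genes named Zfp for 86 of 281 (30.6% against 24%, adjusted p = 0.0229). Mitochondrial ribosomal protein genes (14 of 77, adjusted p = 0.356) and solute carriers (84 of 345, adjusted p = 0.949) did not pass. Probes of a receptor family share sequence, so they are not independent tests. The median between-array SD was 0.0876 for olfactory and 0.1 for vomeronasal receptor genes, above all 10000 random lists of the same size, and 0.0353 for mitochondrial ribosomal proteins.

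The 76 mitochondrial ribosomal protein genes had a median of -0.00561 with 34 positive (camera adjusted p = 0.753). Olfactory receptor genes had a median of -0.0129 with 311 of 733 positive (camera adjusted p = 0.0583), and none of the families passed camera. Of 264 zinc finger genes, 12 were called negative and 1 positive. Probes whose symbol is not that of a hamster gene held an exact 0 more often, at 33.1% of 4402, than those whose symbol is, at 21.2% of 13384 (Fisher's exact p = 6.97e-55); symbols that differ between annotations count as missing here.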
